A study of Danio rerio with 2 samples.

How the data were processed

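Testes and ovaries of adult wild-type zebrafish were isolated and frozen, RNA was extracted with Trizol, and 1 library per organ was sequenced on the BGISEQ-500 platform, per the labels' protocols. Each library came from a pool of 3 adults. The submitters' processing notes name HISAT, Bowtie2 and RSEM and the genome build GRCz10; versions, settings, strand handling and the gene annotation are not given in the sources used here. The authors deposited 1 table with 2 columns of FPKM, 1 per organ, for 24539 Ensembl gene identifiers, per the file headers. FPKM divides the fragments of a gene by its length and by the library's total, so a value is a share of its own library, and a rise in some genes lowers the share of others. Values have 2 decimals. The smallest value is 0.01, held by 430 genes in testis and 3540 in ovary, and it was read as a floor put in place of 0. With 2 genes at the floor in both columns, the table seems to leave out most genes that were not detected in either library. Where copies of a gene are nearly identical (the egg coat genes, numbered clone families, the pimr genes), the division of reads among them is uncertain, and so it is for overlapping and antisense genes. No per-sample column was left unused.

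No read counts were used here and the absolute depth is unknown. The relative depth was estimated from genes with 0.1 to 0.6 FPKM in testis and 0.03 to 0.3 in ovary, 1062 genes. For a gene with few reads, the ratio of its 2 values is a ratio of small whole numbers times the ratio of what 1 read is worth. Ratios piled up at steps of 1 to 1 (82 genes), 2 to 1 (91) and 3 to 1 (61), against 37 genes in an equal window between steps. The position of these steps gave 1.08 for testis over ovary, with an interval of 1.08 to 1.09 from 500 bootstrap draws of genes. In simulated data with known ratios of 0.8, 1.1 and 1.5 the method returned 0.8, 1.1 and 1.5. No ratio under 0.8 was simulated. Candidate ratios up to 2-fold to either side of 1 were scored, but on no step above 3 to 1. A smaller value of 1 read in testis, with these steps as its multiples, was therefore not fully checked. The bootstrap does not measure this.

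Identifiers were named through a table of gene symbols, which named 21881 of the 24539; 11510 of the symbols are in capitals, in the style of human genes, and are printed as given. A total of 1609 symbols are carried by several identifiers. Members of gene lists were matched on the symbol, without regard to case, or else on a single synonym in a RefSeq gene table of the assembly GRCz12tu. That assembly is not the build of the files, so no coordinates are printed, and the table was used only for names and for which genes neighbour each other. Of the symbols written for a list, the matched share was lowest for glycolysis (15 of 42), retinoic acid metabolism (12 of 26), stroma (11 of 23), histones (13 of 27) and sperm (33 of 67), and highest for the egg envelope (16 of 17) and endothelium (18 of 19); symbols carried by several identifiers were left out. A planned comparison of chromosomes was not run for the same reason.

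For each gene the log2 ratio of testis to ovary was computed as log2 of (FPKM + 1) in testis over (FPKM + 1) in ovary. A gene was called higher in an organ when the ratio reached 2-fold and the higher library reached 1 FPKM. With 1 library per organ there is no spread between replicates, so no test across libraries was made. Folds are given between FPKM values, and not against a value at the floor. A total of 30 gene lists for gonadal cell types, germ cell stages, other tissues, core functions and signalling pathways was fixed before the data were examined, as were the size rule and the named genes. A list's median log2 ratio over members that reached 1 FPKM was set against 10000 random lists of the same size, matched on mean log2 expression in 20 bins; its percentile describes these libraries and is not a p-value. In simulated lists of 20 genes among 19053, with 500 random lists each, 7 of 100 lists without any shift lay beyond the central 95%. With shifts of 1, 2 and 4 log2 units, 69, 99 and 100 of 100 did.

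Named genes carry an informative symbol, not a clone or locus name. They are the 12 largest ratios in each direction among genes with at least 10 FPKM in the higher library, the 8 most abundant genes of each library, the 4 members of each list with the highest mean of the 2 libraries, and 26 gonad genes always named where measured, of which 2 (sox9a and foxl2a) were not matched. A few genes that this rule selects are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

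The alternatives were pseudocounts of 0.1 and 5, no minimum or a minimum of 5 FPKM, a 4-fold rule, scaling by a trimmed mean of log ratios (30% of ratios and 5% of abundances trimmed at each end), the median log2 ratio set to 0, rescaling without the 100 most abundant genes of either library (186 genes), other definitions of a gene listed at 0, random lists without matching, and composition without mitochondrially encoded and ribosomal protein genes. A minimum of 10 FPKM and a restriction to genes with a symbol were added after the data were seen. Neighbour pairs were compared with 10000 random placements of the called genes over the same gene order. In simulated data the ratio of observed to random pairs averaged 0.98 for genes placed at random and 5.8 for runs of 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.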

Results

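Gene expression was measured by RNA sequencing in the testis and the ovary of adult wild-type zebrafish. Each organ was represented by 1 library, and each library was made from a pool of 3 adults. The question named in the study's title was which genes and pathways are biased to one sex. The deposited values were FPKM, fragments normalised to gene length and library total, for 24539 genes, with a total of 562394 FPKM in testis and 572635 FPKM in ovary. Read counts were not used here, so the depth of each library is unknown. The steps between the low values were read as 1 to 1, 2 to 1 and 3 to 1. On that reading, 1 read was worth 1.08 times as much FPKM in testis as in ovary (bootstrap interval over genes 1.08 to 1.09). This would put the depth of the ovary library slightly above that of testis, but a smaller ratio with the same steps was not fully checked. With 1 library per organ, no difference described here has a replicate check, and no p-value is given for a difference between the organs. Differences were classed by a fixed rule of size, at least 2-fold on the log2(FPKM + 1) scale among genes that reached 1 FPKM in the higher library; this scale understates the ratio of low genes.

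Many more genes were higher in testis than in ovary, while genes over 1000 FPKM were more numerous in ovary. Of 19053 genes that reached 1 FPKM, 8587 (45.1%) were higher in testis, 3162 (16.6%) were higher in ovary and 7304 (38.3%) differed by less than 2-fold. The testis library held 18303 genes at or over 1 FPKM and the ovary library 12747; 6306 genes reached this level in testis only and 750 in ovary only. At or over 1000 FPKM there were 35 genes in testis and 76 in ovary. Among the 5787 genes whose higher value lay from 1 to 5 FPKM, 56.3% were higher in testis and 5.36% in ovary, against 40.7% and 33.3% of the 1413 genes that reached 100 FPKM. The split depended on how the libraries were scaled. The median log2 ratio of testis to ovary was 0.80 over the genes that reached 1 FPKM, but -0.10 over the 5501 genes at or over 10 FPKM in both libraries. Setting that first median to 0 gave 4777 genes higher in testis and 5779 higher in ovary, so that the testis share of the classed genes went from 73.1% to 45.2%. A trimmed mean of log ratios, a shift of 0.98, gave 4982 and 5780 genes, a testis share of 46.3%. List medians below are given on the deposited scale, and those under about 1 in size have to be read against these shifts.

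**Figure D1:**
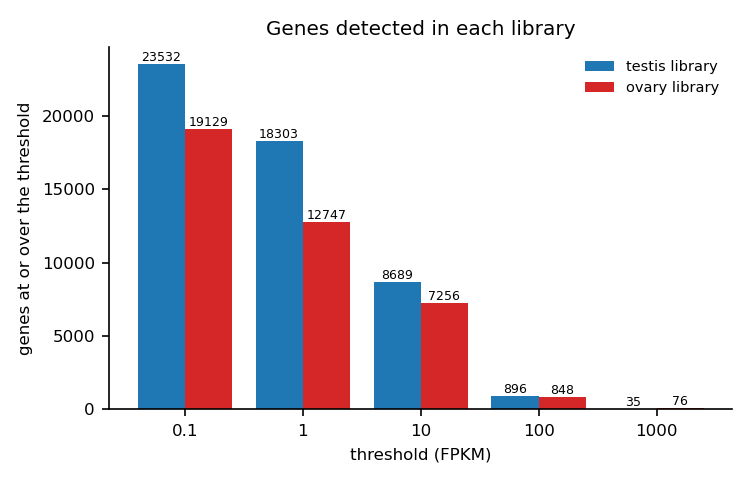
Number of genes at or over 5 FPKM thresholds in the testis library (blue) and the ovary library (red), 1 library per organ. Testis held more genes at each threshold up to 100 FPKM, and ovary held more at 1000 FPKM (76 against 35).

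**Figure D2:**
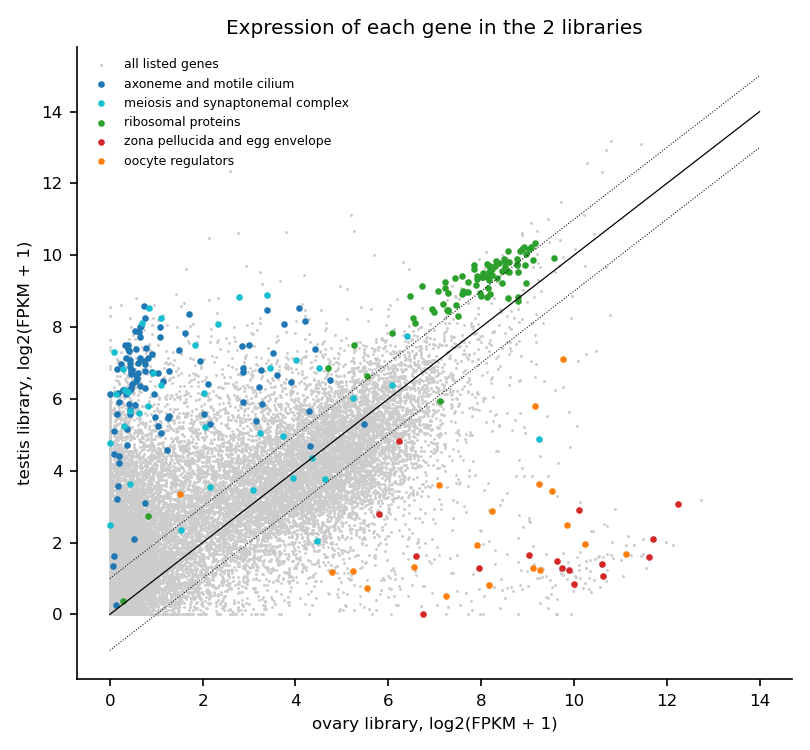
Expression of each listed gene in the ovary library (horizontal axis, log2(FPKM + 1)) and in the testis library (vertical axis, the same unit), with members of 5 gene lists in colour. The solid line marks equal values and the dotted lines 2-fold differences; the axoneme and meiosis genes lie mostly at the upper left, the egg envelope genes at the lower right, and the ribosomal protein genes mostly above the line of equality, by less after rescaling.

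The genes of the egg coat had the lowest median of the 30 gene lists. All 16 measured members of the zona pellucida list, whose proteins build the envelope around the egg, were higher in ovary, with a median log2 ratio of -8.29 (quartiles -9.17 and -6.72). Transcripts of zp2.2 stood at 4862 FPKM in ovary and 7.43 in testis, zp2.1 at 3335 and 3.25, zp2.5 at 3139 and 2.03, and zp3a.1 at 1585 and 1.12. The always-named zp3b stood at 1100 FPKM in ovary and 6.55 in testis. Together the list made up 3.54% of the ovary total and 0.0119% of the testis total. Its members include tandem copies, so the division of reads among zp2.1, zp2.2 and zp2.5 is uncertain. The list's median lay at percentile 0 of 10000 random lists matched on mean expression, as did the medians of the oocyte and maternal lists; percentiles are rounded to 1 decimal and describe these 2 libraries.

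Regulators of the oocyte followed the same direction, with 18 of 19 members higher in ovary and a median of -5.61 (quartiles -7.35 and -3.82). The linker histone gene h1m, whose product packages chromatin in the egg, stood at 2230 FPKM in ovary and 2.18 in testis, cldnd at 1211 and 2.87, ZAR1 at 928 and 4.66, and the cyclin gene CCNB1 at 866 and 136. Genes for the oocyte growth factors read 26.6 against 1.27 FPKM (GDF9) and 93.6 against 1.49 (bmp15). The oocyte transcription factor gene figla read 36.7 against 1.30, and buc, which organises the Balbiani body, read 736 against 9.86. The member that was higher in testis was RGCC, chosen after its values were seen (9.22 FPKM in testis, 1.85 in ovary). Of 16 measured factors that the egg passes to the early embryo, 12 were higher in ovary and 3 in testis, with a median of -4.08. Examples higher in ovary were ca15b (649 against 1.41 FPKM) and slbp2 (531 against 4.98). The 3 higher in testis were YBX1 (980 against 376), DDX4 (440 against 71.6) and hsf1 (24.2 against 8.97, chosen after its values were seen).

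The largest ratios towards ovary also included 2 further members of the zona pellucida list, zp3e (1551 FPKM in ovary, 1.67 in testis) and zp3a.2 (1031 and 0.81). Outside these 3 lists they included the histone gene h2af1al (1676 and 1.35), retsatl (1285 and 1.02), tmsb5 (2285 and 3.51) and zpax4 (929 and 0.97). The identifier ENSDARG00000086859, 1 of 3 that carry the symbol QDPR, stood at 1055 and 1.05 FPKM.

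**Figure D3:**
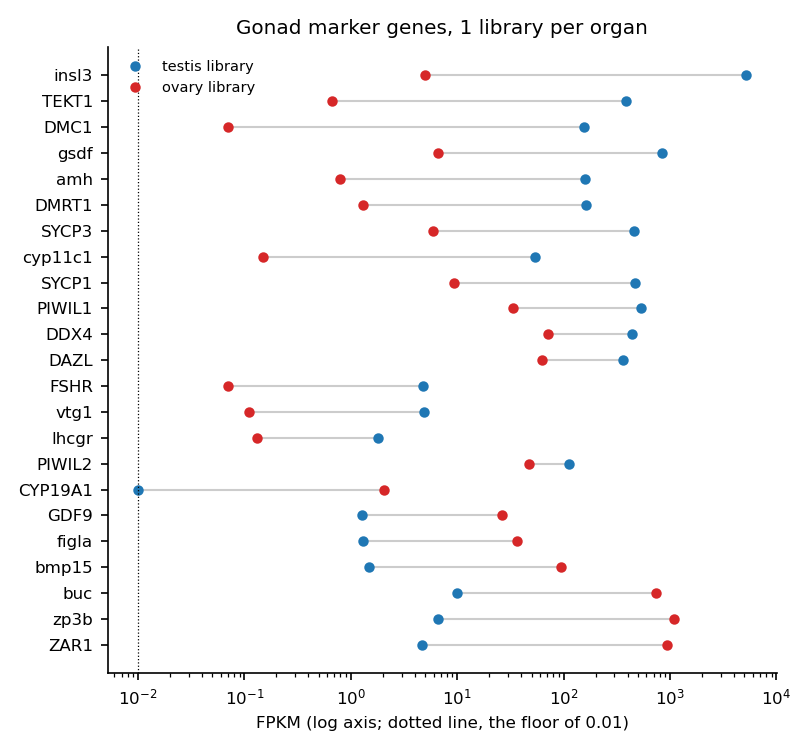
FPKM (log axis) of the gonad genes that were fixed before the data were examined, could be matched and are reported here, in the testis library (blue) and the ovary library (red), ordered by log2 ratio; the dotted line is the floor of 0.01 FPKM. The widest gap towards testis on the log2(FPKM + 1) scale is that of insl3 (5225 against 4.98 FPKM), and the widest towards ovary is that of ZAR1 (928 against 4.66 FPKM).

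Genes of the sperm tail had the highest list median on the testis side. Of 102 measured genes of the axoneme, the microtubule core of motile cilia and flagella, 100 were higher in testis and none in ovary, with a median log2 ratio of 5.53 (quartiles 3.99 and 6.33). TEKT1 stood at 386 FPKM in testis and 0.66 in ovary, ENKUR at 370 and 16.0, and DNALI1 at 354 and 9.48. The 2 members within 2-fold, chosen after their values were seen, were CFAP97 (38.8 and 43.6 FPKM) and cfap99 (24.9 and 18.9). The list made up 2.08% of the testis total and 0.0597% of the ovary total. Intraflagellar transport, which carries parts along the growing cilium, and the BBSome had 36 of 37 genes higher in testis and a median of 2.66. IFT46 stood at 276 against 7.35 FPKM, IFT56 at 194 against 23.4, IFT57 at 153 against 13.1 and IFT81 at 122 against 2.57. The member within 2-fold was BBS4 (15.8 against 11.7, chosen after its values were seen). Other genes with the largest ratios towards testis were the tubulin gene tuba7l (1440 and 3.43 FPKM), CFAP299 (450 and 0.47), SAXO2 (304 and 0.69) and ENSDARG00000100081 (256 and 0.37), 1 of 2 identifiers with the symbol DNAI1.

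Of 33 measured spermatid and sperm genes, 23 were higher in testis and 2 in ovary, with a median of 3.50 (quartiles 0.95 and 5.38). The sperm potassium channel gene cngk read 265 FPKM in testis and 0.87 in ovary, and dydc2 read 263 and 2.29. GAPDHS, which carries the human-style symbol of a sperm form of a glycolytic enzyme, read 232 and 12.8. The identifier ENSDARG00000054191, which carries the human-style symbol PGK2, read 99.0 in testis and 158 in ovary, a difference under 2-fold. The symbol pgk1 of the glycolysis list was not matched to a single gene. The place of this identifier among sperm genes therefore rests on its symbol alone. The 2 members higher in ovary, GOPC (24.4 against 8.0) and septin12 (13.49 against 4.97), were chosen after their values were seen. The medians of the axoneme, transport, sperm and meiosis lists all lay at percentile 100 of matched random lists, and they stayed above 1 after both rescalings.

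Meiotic genes were higher in testis for 30 of 39 members and higher in ovary for 2, with a median of 4.14 (quartiles 1.30 and 5.77). The synaptonemal complex genes SYCP1 and SYCP3, which join paired chromosomes, stood at 473 and 457 FPKM in testis and at 9.40 and 5.88 in ovary. The recombinase gene DMC1 stood at 157 FPKM in testis and 0.07 in ovary, and HORMAD1 at 370 and 0.80. The 2 exceptions were the meiotic cyclin gene CCNA1, at 605 FPKM in ovary and 28.5 in testis, and XRCC2 at 21.2 and 3.09, the latter chosen after its values were seen.

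Germ cell genes that both organs use divided between them. Of 25 measured genes of germ cell identity and the piRNA pathway, which silences transposons, 10 were higher in testis, 4 were higher in ovary and 11 differed by less than 2-fold. PIWIL1 stood at 532 FPKM in testis and 33.5 in ovary, DDX4 at 440 and 71.6, DAZL at 360 and 62.3, and PIWIL2 at 112 and 47.0. In the other direction lay ca15b (649 FPKM in ovary and 1.41 in testis) and 3 genes chosen after their values were seen, namely NANOS3 (58.4 and 1.02), DND1 (23.8 and 7.74) and ZBTB16 (8.15 and 1.51). The piRNA gene gtsf1 read 257 in testis and 385 in ovary. The list's median of 0.53, at percentile 89.6, turned negative under both rescalings (-0.27 with the median ratio set to 0 and -0.43 with the trimmed mean).

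Genes of the somatic cells of the testis were strongly testis-biased. Sertoli cells nurse the developing sperm, and 8 of 9 measured members of their list were higher in testis, with a median of 5.20 (percentile 100). The growth factor gene gsdf stood at 835 FPKM in testis and 6.62 in ovary, krt18a.1 at 206 and 4.65, DMRT1, a transcription factor gene of testis development, at 161 and 1.30, and amh, the gene for anti-Müllerian hormone, at 160 and 0.80. CYP26A1, at 23.0 and 22.4 FPKM, was the member that did not differ by 2-fold (chosen after its values were seen). Of 15 genes of Leydig cells and steroid synthesis, 12 were higher in testis and 2 in ovary, with a median of 2.65 (percentile 100). On the log2(FPKM + 1) scale, the named gene with the largest ratio towards testis was insl3 (ENSDARG00000035862), which encodes a peptide hormone of Leydig cells. It stood at 5225 FPKM in testis, 0.929% of that library, and at 4.98 in ovary, a plain ratio of 1049, which is smaller than the 2238 of DMC1. STAR, whose product brings cholesterol into mitochondria, stood at 385 and 1.88, CYP17A1 at 199 and 30.7, and cyp11c1, needed for 11-oxygenated androgens, at 53.8 and 0.15. The 2 members higher in ovary were fdx1 (178 against 63.3 FPKM) and hsd3b2 (51.6 against 2.12, chosen after its values were seen). Markers of stroma, immune cells, endothelium and blood were also higher in the testis library, with list medians from 1.84 to 3.17.

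The list of granulosa and theca cells, the somatic cells of the ovarian follicle, was not ovary-biased as a share of each library. Of 13 measured members, 8 were higher in testis and 2 in ovary, and the median of 1.47 lay at percentile 57.0 of matched random lists. That median was below those of stroma, immune cells, endothelium and blood (1.84 to 3.17). With a pseudocount of 0.1 it was not the lowest, at 3.05 against 2.88 for immune cells. Expression per follicle cell was not measured. The members higher in testis included inha (137 FPKM against 3.06), INHBB (10.97 against 0.09), RUNX3 (10.1 against 0.28), wnt4b (10.4 against 3.10) and the gonadotropin receptor genes FSHR (4.72 against 0.07) and lhcgr (1.81 against 0.13). Several of these are also used by Sertoli or Leydig cells. The 2 members higher in ovary were CYP19A1, written as cyp19a1a in the list, the gene of the oestrogen-making aromatase, at 2.04 FPKM and at the floor of 0.01 in testis, and foxl2l at 4.29 and 0.49 (chosen after its values were seen). Of 10 measured steroid and gonadotropin receptor genes, 8 were higher in testis and none in ovary, with a median of 1.40 (percentile 89.8). PGR stood at 19.7 FPKM in testis and 1.09 in ovary and NR3C1 at 21.9 and 5.46. PGRMC1 (39.6 and 23.8) and PGRMC2 (42.0 and 81.3) differed by less than 2-fold. Both of these medians fell below 1 with the median ratio set to 0 (0.67 and 0.60) and with a pseudocount of 5 (0.92 and 0.57). With a pseudocount of 0.1 they rose to 3.05 and 2.97.

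Markers of cell types outside the germ line and the gonadal support cells were mostly higher in testis. All 10 measured genes of smooth muscle and stroma were higher there (median 3.17, percentile 99.9), led by SPARC (215 FPKM against 3.56), acta2 (197 against 5.52), col1a1a (66.6 against 6.68) and DCN (21.8 against 0.99). Of 22 immune genes, 20 were higher in testis (median 2.09, percentile 98.7), among them cd74a (118 against 5.21), cd74b (49.9 against 2.42), grna.1 (29.2 against 5.99) and ccl25b (22.3 against 0.34). Of 18 endothelial genes, 16 were higher in testis (median 2.0, percentile 97.3), such as plvapa (14.8 against 0.23), plvapb (11.3 against 1.58) and kdrl (7.08 against 0.99), while stab2 was higher in ovary (8.03 against 3.44). Of 9 erythrocyte genes, 7 were higher in testis (median 1.84, percentile 95.4), including the haemoglobin genes hbaa1 (142 against 12.8) and hbaa2 (19.0 against 0.35) and cahz (50.1 against 0.94); nt5c2l1 read 6.20 against 4.77. Because many of these genes are low in ovary, the medians moved with the pseudocount: that of endothelium was 3.49 with 0.1 and 0.82 with 5 in place of 1, and that of erythrocytes 3.46 and 0.76.

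Genes of the lists for liver, muscle, and pancreas and gut were also detected, mainly in testis. Of 19 measured genes of the liver list, 18 were higher in testis (median 2.41, percentile 100). Among the apolipoprotein genes, apoeb stood at 700 FPKM against 17.3, apoc1 at 269 against 2.49 and apoa1b at 24.6 against 0.33. The retinol carrier gene RBP4 stood at 121 against 2.92. A place in the list does not make a gene particular to liver, and whether this RNA came from liver cells was not tested. The yolk precursor gene vtg1, which the liver expresses in females, stood at 4.90 FPKM in testis and 0.11 in ovary. Of 12 skeletal muscle genes, 11 were higher in testis (median 3.54, percentile 100), with atp2a1 at 67.8 against 1.02, actc1b at 23.6 against 2.07 and pvalb4 at 22.2 against the floor; 5 of the 12 were at the floor in ovary. ENO3 was higher in ovary (454 against 91.9). With pseudocounts of 0.1 and 5 in place of 1, the median was 4.27 and 1.06 for liver and 6.05 and 1.92 for muscle. PVALB, among the largest ratios of all genes, stood at 480 FPKM in testis and 1.70 in ovary. It is not in the muscle list, so it was not read as a muscle gene. The parvalbumin genes written in that list were far lower in testis. Chosen after their values were seen, pvalb1 read 14.4 FPKM there, pvalb2 15.4 and pvalb3 13.0. Of 12 pancreas and gut genes, 9 were higher in testis and 1 in ovary. Their median of 1.25 lay at percentile 55.7, and their levels were low, with ela2 at 9.83 FPKM against the floor, prss1 at 5.19 against 1.65, amy2a at 4.80 against 0.14 and prss59.1 at 4.27 against 0.74. That median fell to 0.46 with the median ratio set to 0 and to 0.91 with the trimmed mean. With a pseudocount of 5 it was 0.49, and with 0.1 it was 2.87. The member higher in ovary was ins (2.70 against 0.45, chosen after its values were seen).

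Cytosolic ribosomal protein genes and mitochondrially encoded genes were mostly higher in testis, whereas most nuclear genes of oxidative phosphorylation, 71 of 102, differed by less than 2-fold. Of 81 ribosomal protein genes, 63 were higher in testis and 1 in ovary, with a narrow spread around a median of 1.29 (quartiles 1.02 and 1.53, percentile 100); the median stayed positive but fell to 0.49 and 0.31 under the median and trimmed mean rescalings. Examples were rpl7a (1211 against 541 FPKM), RPL26 (1208 against 484) and RPS12 (963 against 755). The member higher in ovary was RPL7L1 (138 against 61.1, chosen after its values were seen). All 13 mitochondrially encoded genes were higher in testis, with a median of 1.75 (percentile 100) that fell to 0.95 and 0.77 under the rescalings. MT-CO1 stood at 9323 against 1787 FPKM, mt-atp8 at 8780 against 2801, MT-CO2 at 7790 against 1653, MT-CO3 at 6108 against 1239, MT-ATP6 at 5088 against 1549 and MT-CYB at 2868 against 846. The 102 nuclear genes of oxidative phosphorylation had a median of 0.48 (percentile 98.9), which turned to -0.32 and -0.49 under the rescalings; 26 were higher in testis and 5 in ovary. ATP5F1A (284 against 452 FPKM), ATP5F1B (317 against 376), atp5mc3b (364 against 445) and atp5if1a (96.7 against 575), an inhibitor of ATP synthase, all had the larger value in ovary, with at least 2-fold reached by the last of them. The other 4 higher in ovary, chosen after their values were seen, were atp5mc1, COX7A2L, NDUFAF4 and NDUFAF8. COX5B went the other way, with ENSDARG00000068738, 1 of 2 identifiers of that symbol, at 388 FPKM in testis and 0.94 in ovary. The 48 proteasome genes had a median of 0.91 (percentile 99.8) that came to 0.11 and -0.09 under the rescalings. PSMB2 read 215 against 96.7 FPKM, PSMB4 209 against 112, PSMA8 239 against 150 and PSMA3 173 against 166. Of this list, 22 genes were higher in testis and PSMD10 was higher in ovary (42.0 against 15.5, chosen after its values were seen).

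Energy metabolism included related enzymes with their higher values in opposite organs, and histone genes divided between the organs. The median of 12 measured glycolysis and energy genes was -0.21 (percentile 27.6; -1.01 with the median ratio of all genes set to 0), with 5 higher in testis and 5 in ovary. GAPDH stood at 804 FPKM in ovary and 17.7 in testis, against 12.8 and 232 for GAPDHS. LDHB stood at 327 in ovary and 145 in testis. Chosen after their values were seen, ENO4 (122 in testis and 0.55 in ovary) lay opposite to ENO3 (91.9 and 454), HK1 (4.22 and 0.12) opposite to HK2 (13.4 and 74.3), and ldhbb (17.2 and 4.21) opposite to LDHB. Of 13 histone genes, 6 were higher in testis and 4 in ovary, with quartiles from -1.02 to 5.25 around a median of 0.74 (percentile 89.7) that came to -0.06 with the median ratio set to 0. Those higher in ovary were h1m, h2af1al and, chosen after their values were seen, h2ax (63.7 against 12.7 FPKM) and h3f3a (349 against 172). The variant gene h3f3d read 268 in testis and 334 in ovary.

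Cell cycle genes had no common direction, with 11 of 40 higher in testis, 11 higher in ovary and a median of -0.17 (percentile 14.5; -0.97 with the median ratio set to 0). The most abundant were higher in ovary: the replication licensing inhibitor gene GMNN (956 against 48.8 FPKM), CCNB1 (866 against 136), CCNB2 (681 against 44.9) and CDC20 (388 against 151). RRM2, with 2 identifiers for the symbol, was among the 8 most abundant named genes of ovary (1763 against 322). Of 16 common reference genes, 3 were higher in testis and 3 in ovary, and the median of 0.62 (percentile 93.7) turned to -0.18 and -0.35 under the rescalings. The actin gene actb2 read 1538 in testis and 1373 in ovary, actb1 read 821 and 1648, eef1a1l1 read 2232 and 1185, and ppiaa read 1042 and 592. The 3 higher in testis were b2m (243 and 7.95), RPLP0 (1120 and 384) and RPS18 (547 and 148), and those higher in ovary were actb1, GAPDH and TBP (31.6 and 139); apart from actb1 and GAPDH these were chosen after their values were seen.

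Signalling lists held genes of both directions. Among 26 measured genes of the TGF-beta family pathway, 10 were higher in testis and 8 in ovary (median 0.57, percentile 38.0; -0.23 with the median ratio set to 0). The ligand genes gsdf and amh lay at the testis end and gdf3, a maternal factor of the embryo, at the ovary end (479 FPKM against 4.41), with SMAD5 at 61.3 in testis and 96.6 in ovary. Among 29 Wnt genes, 15 were higher in testis and 8 in ovary (median 1.05, percentile 47.9; 0.25 with the median ratio set to 0). The beta-catenin gene ctnnb2 stood at 198 FPKM in ovary and 81.3 in testis, whereas its paralogue CTNNB1 stood at 92.0 and 88.9; AXIN1 read 35.2 and 13.2 and tcf7l1b 9.81 and 36.0. Among 9 genes of retinoic acid metabolism, 2 were higher in testis and 3 in ovary (median 0.42, percentile 54.7; -0.38 with the median ratio set to 0). ALDH1A2, which makes retinoic acid, stood at 86.0 FPKM in testis and 1.27 in ovary, and RBP4 was higher in testis as well. The receptor gene rarab (73.2 in ovary and 8.83 in testis) and STRA6 (17.4 and 7.52, chosen after its values were seen) were among those higher in ovary.

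**Figure D4:**
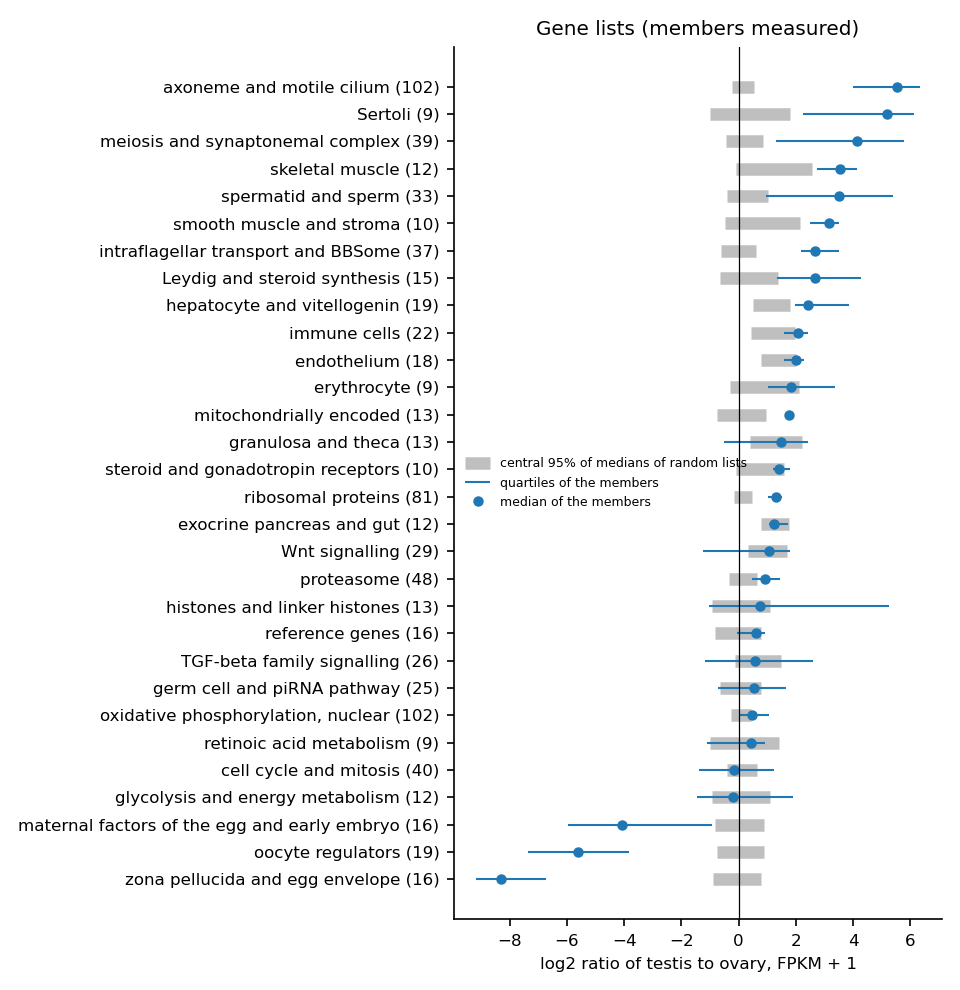
Median log2 ratio of testis to ovary (FPKM + 1) of 30 gene lists, with the number of measured members in brackets; blue lines span the quartiles of the members and grey bars the central 95% of medians of 10000 random lists matched on mean expression. The 3 lists of the egg lie between -8.29 and -4.08, and the axoneme, Sertoli and meiosis lists lie above 4; a shift of 0.80, the median of all genes that entered, would turn the lists plotted between 0 and 0.80 to the ovary side.

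The abundant end of the 2 libraries was made of different genes. The 10 most abundant genes held 9.20% of the testis total and 6.68% of the ovary total, and the 100 most abundant held 24.1% and 27.5%; 14 genes were in both sets of 100. Among genes with an informative symbol, the 8 most abundant of testis were 6 mitochondrially encoded genes, insl3 and eef1a1l1. Those of ovary were zp2.2, zp2.1, zp2.5, mt-atp8, tmsb5, h1m, MT-CO1 and RRM2. Mitochondrially encoded genes held 9.01% of the testis and 2.31% of the ovary total, and ribosomal protein genes 9.35% and 4.01%. Without these genes the order was reversed, and the 10 most abundant held 4.39% of the remaining testis total and 7.13% of the remaining ovary total.

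Genes listed at the floor in one organ and at or over 10 FPKM in the other numbered 189 for the ovary floor and 14 for the testis floor. No fold can be given for them. The testis-expressed ones with a symbol included prok2 (200 FPKM), a secreted peptide gene, and RAB36 (175 FPKM), and 68 of the 189 had no symbol in the table used. Of the 14 at the floor in testis, 12 carried clone or collection names; zp2.6 (107 FPKM in ovary) and tecrl2b (18.6 FPKM), chosen after their values were seen, had gene names. With the depth unknown, a floor value gives no upper limit on expression. Of 246 reference, ribosomal, proteasome and respiratory genes, none was at the floor in testis and 4 were in ovary, the proteasome genes PSMB8, psmb13a, psmb12 and psmb11b.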

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

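The tests with a minimum of 10 FPKM and with only genes that have a symbol were chosen after the data were seen. Genes higher in testis (8587) fell to 4375 with a pseudocount of 5, 5331 with a minimum of 5 FPKM, 4106 with a 4-fold rule and 3770 with a minimum of 10 FPKM, the last 3 by construction; genes higher in ovary (3162) fell to 1180 with the 4-fold rule. With the trimmed mean the counts were 4982 and 5780, and with the median ratio set to 0 they were 4777 and 5779. More genes were then higher in ovary, because both scalings lower testis relative to ovary. The median setting subtracts the same shift from every log2 ratio. The trimmed mean divides the testis values before the pseudocount and the minimum are applied, so genes low in testis move less and 17229 genes entered. Under the other alternatives the counts stayed within 1.5 times, from 7599 to 9557 for testis and from 2234 to 3649 for ovary. Genes listed at 0 in ovary numbered 348 at 5 FPKM, 23 at 50 FPKM and 315 with values up to 0.1 FPKM read as 0, against 189, and those listed at 0 in testis numbered 27 at 5 FPKM, against 14. Without mitochondrial and ribosomal protein genes, the 10 most abundant genes held 4.39% of testis and 7.13% of ovary and the 100 most abundant 15.1% of testis. Of the 30 lists, 18 had a median at least 2-fold higher in testis and 3 in ovary; the testis number ranged from 12 to 19 over the alternatives, and the ovary number was 5 with the trimmed mean. No list or named gene with a ratio of at least 2-fold changed sign under the alternatives run, but 15 of 124 such named genes fell under 2-fold with the median set to 0, 16 with the trimmed mean and 10 with a pseudocount of 5. The authors' own ratios, a second unit and the chromosome comparison were not run. Depth is unknown, and with 1 library per organ the spread between animals is too. No paired analysis was possible because each organ has 1 library.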

Other observations

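The tests in this part were chosen after the values were seen, except 2 of them: the neighbour test and the count of detected genes without the most abundant ones. Gene families were read from the letters that begin a symbol, for 281 beginnings with 8 or more measured genes, and 18 lay above and 20 below the central 95% of matched random lists, where chance gives 14 in all at the nominal rate; in simulated lists without a shift, 7 of 100 lay beyond this range. All 98 measured genes of the pimr family, which are related to the Pim kinases, were higher in testis, with a median log2 ratio of 3.53 (2.73 with the median ratio of all genes set to 0); 53 of them were at the floor in ovary. The most abundant were pimr184 (121 FPKM in testis, at the floor in ovary), pimr62 (89.3 against 0.57) and pimr60 (77.3 against 0.45), and reads shared among their copies leave single members uncertain. The 9 measured rfx genes, for transcription factors that include regulators of cilia, were all higher in testis (median 2.22), such as rfx3 (121 against 11.6 FPKM). Of 11 ttll genes, for enzymes that modify tubulin, 8 were higher in testis and 1 in ovary (median 3.53), with TTLL3 at 83.8 against 1.2 and ttll4 in the other direction at 32.4 against 68.0. NME5 (164 against 0.40) stood out among 9 nme genes, of which 7 were higher in testis.

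The families below were picked from the low end of the same ranking, and they do not stand for RNA processing as a whole: the splicing factor genes srsf had 8 of 17 higher in testis and 3 in ovary (median 0.69, and -0.11 with the median ratio of all genes set to 0), the lsm genes had 5 of 15 in each direction (percentile 42.4), and the ddx helicase genes lay at percentile 30.7. Of 17 trmt genes, which methylate transfer RNA, 11 were higher in ovary and none in testis (median -1.58, and -2.38 with the median ratio of all genes set to 0), for example TRMT2A (45.0 FPKM in ovary against 8.79 in testis). Of 10 exosc genes of the RNA exosome, 7 were higher in ovary and none in testis (median -1.41), led by EXOSC6 (82.3 against 9.60), and of 10 utp genes of ribosomal RNA processing, 8 were higher in ovary and none in testis (median -1.28), such as utp3 (69.5 against 25.8). Of 46 mrpl genes, for proteins of the large mitochondrial ribosomal subunit, 22 were higher in ovary and 2 in testis (median -0.87, percentile 0.31). Examples are MRPL17 (115 against 36.4) and MRPL14 (111 against 31.5). The 27 mrps genes had a median of -0.82, inside the central 95% of random lists at percentile 3.07. Of 15 timm genes of mitochondrial protein import, 7 were higher in ovary and none in testis (median -0.96), with TIMM8B at 83.6 against 19.1. The tomm genes, also of mitochondrial import, had 2 of 10 higher in ovary and 1 in testis (percentile 17.6). Unrelated beginnings lay as low against random lists, such as zbtb (percentile 0.25), unc (0.28) and elovl (0.55), so the families named here are a selection.

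Of 76 genes at or over 1000 FPKM in ovary, 61 stood under 1% of that level in testis, with the lowest share at 0.041%. The shares under 1% lay in a narrow band, with a median of 0.11% and 10th and 90th percentiles of 0.056% and 0.27%. Of the 35 such genes of testis, 4 stood under 1% in ovary, the lowest being insl3 at 0.095%. Whether such low values are expression in the organ where they were read was not tested.

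Markers of 4 other cell types had lower medians in the ovary library. Off the floor, and without a pseudocount, the median testis to ovary ratio was 16.3 for stroma, 14.8 for endothelium, 11.1 for erythrocytes and 8.50 for immune cells, and 55 of 57 genes had the larger value in testis; no member of the 4 lists belongs to another list, and 22 of the 65 matched members reached 1 FPKM in ovary. The 100 most abundant genes taking the ovary total is argued against. Without the 100 most abundant genes of either library the pooled median log2 ratio was still 3.27, against 3.43 with them. Leaving them out is a log2 shift of only -0.16 for every gene, so this does not bear on a larger set of ovary genes. A second candidate explanation is that oocyte RNA dilutes that of every other cell in the ovary by 1 factor; the 4 medians spanned 0.94 log2 units, wider than the 0.5 set for a common factor, yet 100000 permutations of genes among the lists gave a range as wide with p = 0.451, and the bootstrap interval of the erythrocyte median alone ran from 0.38 to 5.74. The values therefore decide neither for nor against 1 factor, and a true difference in the cell makeup of the organs was not tested and stays open.

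More genes were detected in testis than in ovary, by 5556 at 1 FPKM. The step estimate, with 1 read worth 1.08 times as much FPKM in testis (1.08 to 1.09), puts the deeper library on the ovary side. It does not exclude deeper sequencing of testis, because a smaller read value there, with the steps as its multiples, was not fully checked. Crowding by the 100 most abundant genes of either library is argued against, because the excess was still 5509 genes without them. Leaving them out is a log2 shift of only -0.16, whereas the trimmed mean is a shift of 0.98. The excess was not counted under the trimmed mean, where 17229 genes reached 1 FPKM in place of 19053. The depth and crowding by a larger set of ovary genes stay open. So does a difference between the organs themselves, including the number of cell types that contribute RNA, which was not tested. With 1 library each, the preparation of either library stays open as well.

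Genes higher in ovary were neighbours in the order of the placed genes more often than chance, as hypothesised before the test. The order was that of GRCz12tu, and genes that could not be placed may lie between neighbours. Among 12935 genes placed by symbol, 511 of 12910 neighbour pairs were both higher in ovary, against 424 on average and 483 at most in 10000 random placements, a ratio of 1.21. Near-identical tandem copies that share reads may contribute: among the longest runs, 1 held zp2.2, zp2.3, zp2.6, zp2.1 and zp2.5 and another 5 gbgt1l genes. With neighbours of the same symbol beginning or clone left out the ratio was 1.15 (471 pairs against 408, highest random value 468), which lies between the bounds set in advance, so shared copies and a true grouping of ovary genes cannot be told apart here; clone-named copies on different clones were not removed. Genes higher in testis also lay together more often than in any random placement (2344 pairs, highest random value 2340), at a ratio of 1.05; without such neighbours their ratio was 1.01, at percentile 66.3.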
